A study of Homo sapiens with 12 samples.

How the data were processed

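The signal values were deposited by the authors as a table of normalized counts, 1 value per gene and library, for 28035 genes. Each library's values turned into whole numbers when multiplied by 1 factor per library, with 100% of values within 0.01 of a whole number, so reads per gene were recovered by that factor and the depth given for each library is their sum. The log2 values of the authors' deposited tables are fold changes between 2 groups, and their p-values and adjusted p values are as deposited, per the file headers in the column layout of DESeq2. The authors' deposited table of the Combination against DMSO came from a separate fit. Its mean column equals the mean of its own 6 libraries, times 0.979, in 100% of its 25780 genes, while in the other 5 tables the column equals the mean of all 12 libraries in 100% of 28035 genes. The submitters' processing notes name bcl2fastq 2.20, STAR 2.7.3, FastQC and DESeq2 1.24.0 with the genome build hg19. The counting program, the gene annotation and the role of each tool are not given in the sources used here. Genes with near-identical copies, such as histone, HLA, IFIT and HSPA1 genes, are therefore uncertain where reads could be shared between copies.

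Groups and replicate numbers were taken from the labels. Libraries came from 100 ng of RNA with a stranded poly(A) kit, per the labels. Values of histone genes therefore stand mainly for their transcripts with a poly(A) tail. Gene names were used as deposited, and 4 list symbols were matched through older names (GCN1L1, IL8, C12orf5 and DFNA5). No coordinates were used, because the reference at hand is of another genome build. The tests, thresholds, gene lists and most alternatives were chosen before the data were examined. The comparisons without replicate 3 and with a term for replicate 3 were chosen after the data were seen.

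Genes with a mean of at least 10 normalized reads over the 12 libraries were tested, 15990 in all, and 12045 were left out. Values were analysed as log2 of the normalized value plus 1, which understates the fold change of genes with few reads. limma 3.58.1 in R 4.3.3 fitted 1 model to the 12 libraries with a mean for each of the 4 groups and a variance trend. Moderated t-tests were two-sided, and p was adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. The 6 pairwise comparisons and the interaction (the FC-A effect with IFNa minus that without) were contrasts of that model. Fold changes are 2 raised to the log2 value, SE is the moderated standard error of the log2 value, and SD is the standard deviation of normalized reads over 3 libraries.

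Genes were named by a rule set before the data were examined. For each comparison the rule takes up to 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold with a mean of at least 50 normalized reads and no overlap between the 3 libraries of each group. Chance alone separates 3 libraries from 3 others in 10% of genes. It adds up to 3 members of each list with the largest change past the threshold, and 14 genes fixed beforehand (among them YWHAB, YWHAE, YWHAG, YWHAH, YWHAQ, YWHAZ, SFN, GCN1L1, EIF2AK4, ATF4, IFNAR1, IFNAR2 and RIPK2). Where fewer than 5 genes passed, the 5 with the smallest p were taken and given by value. The text names a part of these.

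The 28 gene lists were written from general knowledge and tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 28 lists of a comparison. They cover type I interferon-stimulated genes, the interferon receptor with JAK-STAT and feedback, MHC class I presentation, interferon-inducible chemokines and ligands, cell death, ATF4 targets, the unfolded protein response, 14-3-3 proteins, the GCN1, GCN2 and eIF2 kinase genes, and targets of p53, NF-kB, MAPK, YAP, FOXO, the estrogen receptor, TFEB, SREBP with cholesterol synthesis, NRF2, heat shock and hypoxia. The others hold DNA replication, mitosis, histone and mitochondrially encoded genes and markers of ovarian epithelium, fibroblasts, immune cells and endothelium. In all, 3 genes sit in more than 1 list. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the genes of that list only. With an estimated correlation camera used the correlation measured in each list. Of the lists called at the preset value, 1 of 7 kept its call for FC-A against DMSO (cholesterol), 6 of 14 for IFNa, 6 of 15 for the Combination against DMSO, 0 of 14 for the Combination against IFNa, 6 of 15 against FC-A, 6 of 16 for FC-A against IFNa and 1 of 9 for the interaction (cholesterol).

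Alternatives were pseudocounts of 0.5 and 8, no filter, a minimum mean of 50, TMM and quantile scaling, no variance trend, a fit of the compared groups only, the replicate number as a block, each library left out, a fold threshold of 2, the authors' deposited tables, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered reads. Leaving out a library of a group outside a comparison changes the estimate of the spread, and so the p-values, but no fold change. Lists were also tested with fry. For the chance of a grouping, the 6 libraries of a comparison were split in all 10 ways into 3 and 3. The axis of replicate 3 was the log2 difference between replicate 3 and replicates 1 and 2 over all groups. For lists, the trend of a comparison on that axis across genes was removed and the rest tested with cameraPR.

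A self-test put known changes into simulated counts for 15990 genes, for FC-A against DMSO and for the interaction only. The changed genes were drawn from those with a mean of at least 50 normalized reads, so recovery below that mean was not measured. All groups started from the DMSO means, so no response to IFNa was simulated. Of 50 genes changed at each size in FC-A against DMSO, limma recovered 23 at 1.3-fold, 35 at 1.5-fold, 46 at 2-fold and 50 at 4-fold, with 2 false calls. edgeR recovered 26, 40, 47 and 50 with 9 false calls, and DESeq2 29, 41, 47 and 50 with 20 false calls. For the interaction limma recovered 12, 25, 44 and 50 with 8 false calls, edgeR 12, 26, 44 and 50 with 8, and DESeq2 18, 34, 45 and 50 with 22. A shift of -0.15 in the 22 G1/S genes was recovered as lower (adjusted p = 0.000302), and 0 of the 27 other lists were called. The simulated genes were drawn independently of each other, without the deviation of replicate 3. The self-test therefore cannot show how often camera calls lists whose genes move together between libraries. Raw sequence reads were not used here.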

Results

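Messenger RNA was sequenced from OVCAR-3 cells, an established human ovarian adenocarcinoma line, collected after 6 h of treatment. The 12 libraries fell into 4 groups of 3. Cells received the vehicle DMSO, Fusicoccin A (FC-A, a fungal glycoside that stabilises complexes between 14-3-3 adapter proteins and their partners), interferon alpha (IFNa, a secreted antiviral cytokine), or both agents (the Combination group). The doses are not given in the sources used here. Reads assigned to genes came to 35.9, 33.9 and 33.8 M in the DMSO libraries, 36.7, 33.4 and 34.5 M with FC-A, 36.4, 39.5 and 33.2 M with IFNa and 35.1, 31.2 and 34.5 M in the Combination. Of 28035 listed genes, 15990 were abundant enough to test. The median standard error of a log2 fold change between 2 groups was 0.0924.

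The cells kept the transcripts of an ovarian epithelium in every group. EPCAM, an epithelial adhesion molecule, averaged 8917 normalized reads in DMSO and 8703 in the Combination, and PAX8, a transcription factor of the Müllerian lineage, averaged 17710.0 in DMSO. PTPRC, the leukocyte marker CD45, averaged 10.2 normalized reads in DMSO, and other markers of that list were higher, with CD14 at 199.8 and CSF1R at 37.2. Of the fibroblast markers COL1A1 averaged 814.7 and DCN 0. The first principal component held 77.7% of the variance and separated the 6 libraries that received IFNa from the 6 that did not. The next component held 6.51%, and replicate 3 lay lowest on it in each group. FC-A replicates 1, 2 and 3 were spread along it (13.4, -3.65 and -23.4). It also set IFNa replicates 1 and 2 (16.5 and 24.3) apart from Combination replicates 1 and 2 (-2.36 and -4.47). A comparison of replicate 3 with the other replicates of all groups, made after the data were seen, called 3564 genes, 1562 higher and 2002 lower. Every comparison was therefore also run without replicate 3. Nothing states that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

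FC-A without IFNa raised DDIT4, whose product restrains the growth kinase mTORC1, 1.56-fold (log2 fold change 0.64, SE 0.09, n = 3 per group, limma adjusted p = 0.00659), from 3655 ± 140 to 5711 ± 479 normalized reads (mean ± SD). SCD, which desaturates fatty acids, rose by 0.58 on the log2 scale (SE 0.07, adjusted p = 0.00236), from 11438 ± 507 to 17172 ± 1474 normalized reads. INSIG1, which holds the sterol sensor in the endoplasmic reticulum, rose 1.40-fold (SE 0.06, adjusted p = 0.00431). CPA4, a secreted carboxypeptidase, fell 2.12-fold (SE 0.07, adjusted p = 3.77e-06), from 3664 ± 103 to 1732 ± 88.3 normalized reads. IQGAP2, a scaffold of the cytoskeleton, fell 1.57-fold (SE 0.06, adjusted p = 0.000327), and MMP10, a secreted matrix protease, fell 1.92-fold (SE 0.11, adjusted p = 0.00231).

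The question here was what FC-A changed by itself at 6 h. It raised 25 genes and lowered 23, 48 in all. Only 3 of them changed at least 2-fold, and these were CPA4, FAM65B and the histone gene HIST1H3D, the last named after its values were seen. Genes of cholesterol synthesis and sterol regulation rose together. Of 24 tested, 8 rose, none fell and 16 did not pass, 17 rose when adjusted over the list alone, and 23 had a positive fold change (median log2 fold change 0.30, camera adjusted p = 2.48e-27). This was the only list of the 7 called for FC-A that kept its call with an estimated correlation (adjusted p = 0.00054). Its members included SCD, INSIG1 and the mevalonate enzyme MVD (log2 fold change 0.44, adjusted p = 0.00231). Without replicate 3 the list's adjusted p was 5.84e-30.

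Targets of ATF4, the transcription factor of the integrated stress response, moved upward as a set by a small amount. Of 39 genes, DDIT4 rose and 38 did not pass, 7 rose when adjusted over the list alone, and 35 had a positive fold change (median 0.06, camera adjusted p = 1.79e-07). With an estimated correlation the adjusted p was 0.247. DDIT4 lost its call without DMSO replicate 2 (adjusted p = 0.0592) and had an adjusted p of 4.74e-05 without replicate 3. The ATF4 gene itself measured 0.08 on the log2 scale (SE 0.05, adjusted p = 0.72).

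Among growth regulators, MYC, a transcription factor that drives proliferation, fell 1.38-fold (SE 0.07, adjusted p = 0.00877), from 888 ± 10.9 to 646 ± 44.4 normalized reads. CDKN1A, the cell cycle inhibitor p21, rose 1.34-fold (SE 0.07, adjusted p = 0.0183), and RGCC, a cell cycle regulator, fell 1.61-fold (SE 0.09, adjusted p = 0.00544). PDE4B, which degrades cyclic AMP, fell 1.58-fold (SE 0.09, adjusted p = 0.00471), and CLIC5, a chloride channel family protein, fell by 0.77 on the log2 scale (SE 0.11, adjusted p = 0.00659). In the immediate early and MAPK list MYC fell, IER2 rose by 0.31 on the log2 scale (adjusted p = 0.0463) and 24 of 26 genes did not pass (2 higher and 1 lower when adjusted over the list alone), with a list adjusted p of 0.963 (median -0.04, mean 0.01, tested lower). CDKN1A was the 1 gene of 18 p53 targets that rose, also when adjusted over the list alone (median -0.01, mean 0.02, list adjusted p = 0.736 on the higher side). The calls of MYC and CLIC5 were lost without DMSO replicate 1 (adjusted p = 0.059 and 0.053), DMSO replicate 2 (0.0649 and 0.0592) or FC-A replicate 2 (0.0502 and 0.0524), and all of the genes in this paragraph were called without replicate 3. CDKN1A was not called without DMSO replicate 1, 2 or 3 or FC-A replicate 2 or 3 (adjusted p from 0.0542 to 0.131), and IER2 not without any of 9 libraries (0.0598 to 0.225), namely the DMSO libraries and replicates 2 and 3 of FC-A, 1 and 2 of IFNa and 1 and 2 of the Combination.

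With FC-A alone, none of 52 interferon-stimulated genes passed limma's test (2 higher and 2 lower when adjusted over the list alone), the list median was 0.02 with a mean just below 0, tested on the higher side, and its adjusted p was 0.662. The 11 interferon-inducible chemokines and ligands had a median of -0.23 with 0 genes past the threshold, 2 lower when adjusted over the list alone and a list adjusted p of 0.0056. That list was not called with an estimated correlation (adjusted p = 0.247), without FC-A replicate 3 (0.188) or without replicate 3 of every group (0.0899). Several of its genes had few reads without IFNa. In the DMSO and FC-A libraries CXCL11 stood at 0 to 1.782 normalized reads and TNFSF13B at 0 to 0.891. Both passed the filter only through the libraries that received IFNa. CXCL10 stood at 7.358 to 14.51 and IDO1 at 8.91 to 31.46, so the list's decrease rests partly on values near 0. None of the 7 genes that encode 14-3-3 proteins passed (medians of -0.07 with FC-A alone and -0.03 with FC-A on top of IFNa, list adjusted p = 0.331 and 0.875), and neither did GCN1L1 or the other 6 genes of the GCN1, GCN2 and eIF2 kinase list (adjusted p = 0.386 and 0.343).

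The YAP, histone, hypoxia and G1/S lists were also called for FC-A alone, none of them with an estimated correlation. Of 18 YAP and TEAD targets, CRIM1, a transmembrane regulator of growth factors, fell by 0.38 on the log2 scale (adjusted p = 0.0437) and 17 did not pass. The list had a median of -0.10, 3 genes lower when adjusted over the list alone and an adjusted p of 0.00128, or 0.705 with an estimated correlation. It was not called without FC-A replicate 3 (adjusted p = 0.0932), and replicate 3 of all groups was itself lower for 12 of its 18 genes. CRIM1 had an adjusted p of 0.0575 to 0.242 without any DMSO library, FC-A replicate 2 or 3, IFNa replicate 1 or Combination replicate 1 or 2. The 8 tested genes of the fixed list of replication-dependent histones all had positive values (median 0.29, adjusted p = 0.000103, or 0.319 with an estimated correlation) and none passed. HIST1H3D, which passed (log2 fold change 1.05, adjusted p = 0.0449), is not on that list and was named after its values were seen. Because the kit selects poly(A) RNA, these histone values stand mainly for transcripts with a poly(A) tail. Hypoxia and glycolysis genes had a median of 0.15 with 0 of 19 passing (adjusted p = 0.0221, or 0.709 with an estimated correlation), and their adjusted p was 0.207 without DMSO replicate 3, 0.188 without FC-A replicate 3 and 0.476 without replicate 3 of every group. DNA replication and G1/S genes had a median of -0.10 with 0 of 22 passing (adjusted p = 0.0387, or 0.876 with an estimated correlation). Without FC-A replicate 3 the G1/S list turned to the higher side (adjusted p = 0.878), without DMSO replicate 1 or 2 its adjusted p was 0.12 or 0.161, and without replicate 3 of every group it was 0.476.

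The count for FC-A alone depended on the tool and on which libraries entered. edgeR called 48 genes and DESeq2 171 on the recovered reads, the authors' deposited table held 155, and 134 were called without replicate 3, among them 47 of the 48. Leaving out DMSO replicate 1, 2 or 3 left 17, 16 or 18 genes, FC-A replicate 2 left 19, IFNa replicate 1 left 26, and leaving out FC-A replicate 1 or IFNa replicate 3 gave 119 or 85. The IFNa libraries do not enter the fold changes of this comparison, only the estimate of the spread.

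**Figure D1:**
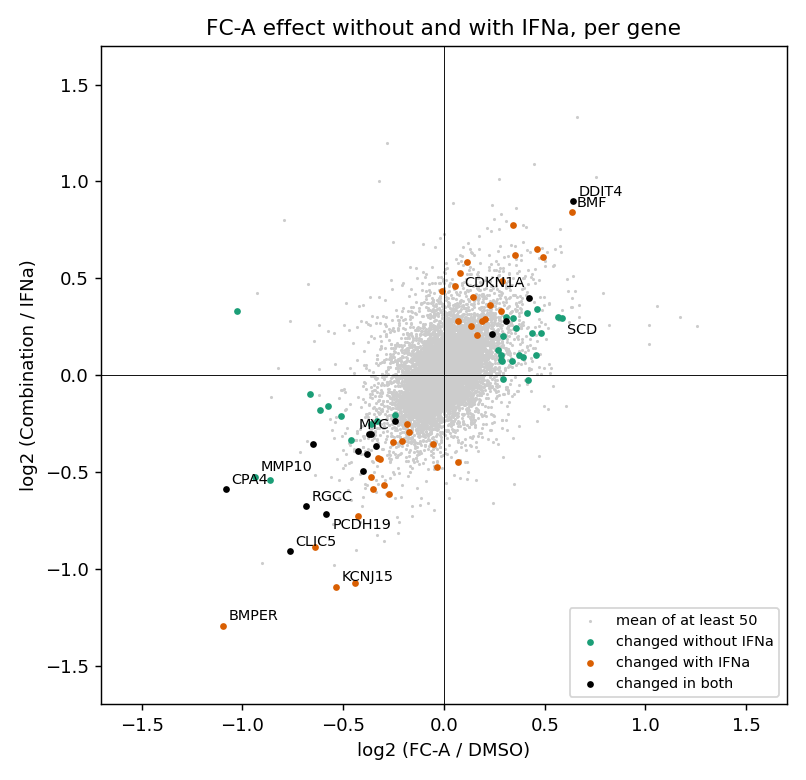
Log2 fold change of each tested gene with a mean of at least 50 normalized reads for FC-A against DMSO (horizontal axis) and for the Combination against IFNa (vertical axis). CPA4 lies at -1.08 and -0.59, DDIT4 at 0.64 and 0.90, and SCD at 0.58 and 0.30.

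IFNa alone turned on the antiviral program. OAS2, which makes the activator of the antiviral nuclease RNase L, rose from 25.0 to 31541 normalized reads (log2 fold change 10.30, SE 0.26, n = 3 per group, adjusted p = 2.17e-13). RSAD2, the antiviral protein viperin, rose from 48.8 to 18860.0 (380-fold, adjusted p = 1.32e-16), and CXCL10, a chemokine that draws T cells, rose from 13.4 to 14923 (1038-fold, adjusted p = 9.59e-16). BMF, a BH3-only protein that promotes apoptosis, fell 6.60-fold (SE 0.13, adjusted p = 5.01e-10), and LMO1, a transcription cofactor, fell 7.12-fold (adjusted p = 3.07e-10).

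This comparison gave the response to the cytokine that the Combination is set against. In all, 7507 genes changed, 4067 higher and 3440 lower, and 928 rose and 511 fell at least 2-fold. edgeR called 7533, DESeq2 7388 and the authors' deposited table listed 7291, and without replicate 3 the count was 7580. The summed normalized reads averaged 37.0 ± 0.687 M with IFNa against 32.4 ± 0.177 M in DMSO. Under quantile normalization the median log2 fold change of all genes was -0.0991, against -0.0065 in the main analysis. The share of higher calls went from 54.2% to 36.6%, while it was 54.1% with TMM scaling, 52.6% with edgeR and 53.7% with DESeq2.

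**Figure D2:**
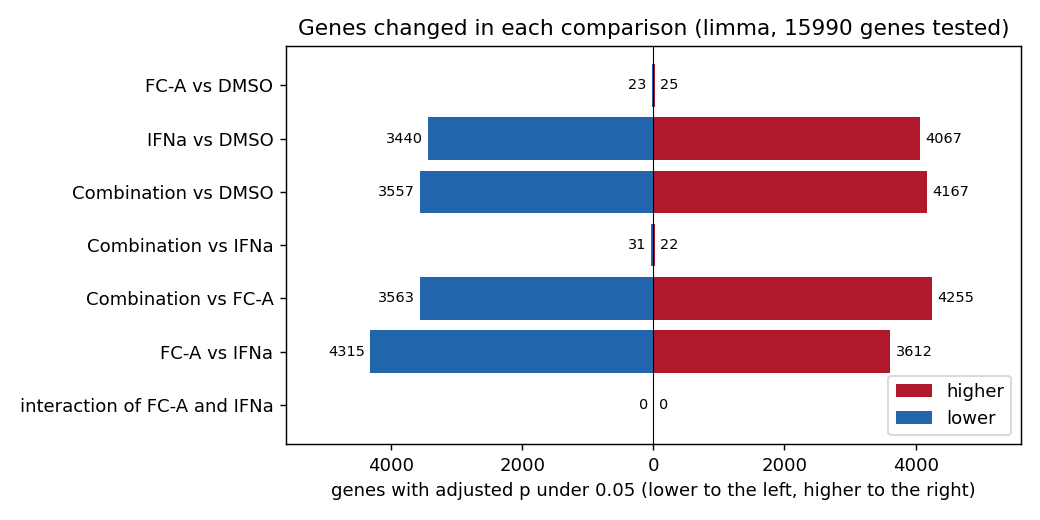
Number of genes called higher (right) and lower (left) in each comparison by limma, on a linear axis. FC-A changed 48 genes without IFNa and 53 with it, against 7507 for IFNa alone.

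All 52 interferon-stimulated genes rose, also when adjusted over the list alone (median 4.89, list adjusted p = 6.05e-63, or 0.00346 with an estimated correlation), among them IFIT1 (392-fold) and IFIT2 (329-fold), whose paralogs share sequence, so their values are uncertain if reads were split. Of 19 genes of the interferon receptor, JAK-STAT and feedback list, 15 rose, none fell and 4 did not pass, with the same 15 when adjusted over the list alone (list adjusted p = 9.13e-12, or 0.00564 with an estimated correlation). They included USP18, which shuts the receptor down (27.7-fold), IRF7 (20.6-fold) and IFNAR2 (1.25-fold, adjusted p = 0.00105). All 19 genes of MHC class I presentation rose (19 over the list alone, median 2.28, adjusted p = 1.58e-22, or 0.0104 with an estimated correlation), such as the peptide transporter TAP1 (22.8-fold) and the immunoproteasome subunit PSMB9 (19.9-fold). HLA genes in that list are near copies of each other, which makes their single values uncertain. All 11 chemokines and immune ligands rose (11 over the list alone, median 3.57, adjusted p = 5.1e-11, or 0.00346 with an estimated correlation).

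Genes of the cell death list moved mostly upward. The list also holds inhibitors of death, such as XIAP and CFLAR, so its counts give no direction for cell death itself. Of its 39 genes, 26 rose, 7 fell and 6 did not pass (27 and 7 over the list alone, median 0.95, adjusted p = 2.71e-10, or 0.00166 with an estimated correlation). TNFSF10, the death ligand TRAIL, rose 37.4-fold (SE 0.08, adjusted p = 9.19e-16), from 525 to 19650.0 normalized reads, and ZBP1, a sensor that can start necroptosis, rose from 7.19 to 399 normalized reads. BMF went the other way, as given above. RIPK2, a kinase of the NOD receptors, rose 3.37-fold (SE 0.12, adjusted p = 2.33e-08). CDKN1A rose 3.76-fold (SE 0.07, adjusted p = 1.5e-11), while of 18 p53 targets 5 rose, 11 fell and 2 did not pass (5 and 11 over the list alone, list adjusted p = 0.144), BTG2 falling 2.58-fold.

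Immediate early genes and inflammatory genes rose. In the immediate early and MAPK list 24 of 26 rose, none fell and 2 did not pass (24 over the list alone, adjusted p = 5.23e-14, or 0.0033 with an estimated correlation), led by FOSL1 (log2 fold change 3.46) and the feedback inhibitor SPRY4 (9.28-fold). Of 22 NF-kB and TNF response genes 20 rose, none fell and 2 did not pass (21 over the list alone, median 1.93, adjusted p = 7.99e-14), with an adjusted p of 0.0806 with an estimated correlation. They included the chemokines IL8 (log2 fold change 4.46) and CX3CL1 (21.9-fold).

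Stress and metabolism lists rose in part, and none of these kept its call with an estimated correlation. Of 39 ATF4 targets 21 rose, 5 fell and 13 did not pass (22 and 5 over the list alone, median 0.24, adjusted p = 0.00148, or 0.284 with an estimated correlation). NUPR1, a stress-induced chromatin protein, rose 5.99-fold, CHAC1, which degrades glutathione, 2.83-fold, and ATF4 itself 1.43-fold (SE 0.05, adjusted p = 8.72e-07). Of 19 genes of the unfolded protein response 14 rose, none fell and 5 did not pass (15 over the list alone, adjusted p = 0.00044, or 0.282 with an estimated correlation), led by HERPUD1 (1.53-fold). Hypoxia and glycolysis genes rose in 10 of 19 cases with 9 not passing (10 over the list alone, adjusted p = 0.00105, or 0.282 with an estimated correlation), ADM by 3.37-fold. YAP and TEAD targets rose in 13 of 18 with 5 not passing (13 over the list alone, median 0.72, adjusted p = 0.000324, or 0.284 with an estimated correlation), NT5E by 9.50-fold. Heat shock genes rose in 8 of 13, 1 fell and 4 did not pass (8 and 1 over the list alone, adjusted p = 0.0118, or 0.595 with an estimated correlation), DNAJA1 by 2.22-fold. Estrogen receptor targets rose in 7 of 13, 1 fell and 5 did not pass (7 and 1 over the list alone, adjusted p = 0.0381, or 0.133 with an estimated correlation), the cyclin CCND1 by 2.68-fold.

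Mitotic genes fell with IFNa. Of 21 genes of mitosis and G2/M, 20 fell and 1 did not pass (20 over the list alone, median -0.54, adjusted p = 9.11e-10, or 0.282 with an estimated correlation). CDC25C, the phosphatase that starts mitosis, fell 2.05-fold (SE 0.11, adjusted p = 3.5e-06) and the checkpoint kinase BUB1B fell 1.90-fold (SE 0.08, adjusted p = 2.59e-07). Replicate 3 of all groups was also lower for 15 of the 21, and without it the list's adjusted p was 7.81e-12. Of 22 DNA replication and G1/S genes, GINS1 rose, E2F2 and E2F1 fell and 19 did not pass (1 and 2 over the list alone, list adjusted p = 0.687), and E2F1 lost its call without IFNa replicate 3 (adjusted p = 0.0629).

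The 14-3-3, GCN1 and cholesterol lists were not called for IFNa, though single members changed. YWHAG (log2 fold change 0.57), YWHAH (0.43), SFN (0.33) and YWHAZ (0.17) rose, 4 of 7 genes for 14-3-3 proteins, also over the list alone (list adjusted p = 0.0794), but under quantile normalization YWHAZ, YWHAB, YWHAE and YWHAQ turned negative and YWHAH (adjusted p = 0.0684) and SFN (0.0536) no longer passed. YWHAZ was also lost without IFNa replicate 1 (adjusted p = 0.0506). In the GCN1, GCN2 and eIF2 kinase list, EIF2AK2, the double-stranded RNA kinase PKR, rose 7.30-fold and EIF2S1 1.22-fold, EIF2AK4, which encodes GCN2, fell 1.22-fold (adjusted p = 0.00376) and 4 did not pass (2 and 1 over the list alone, list adjusted p = 0.533), with the EIF2S1 call lost under quantile normalization (adjusted p = 0.38). Cholesterol genes were split, with 7 higher, 2 lower and 15 not passing of 24 (7 and 2 over the list alone, list adjusted p = 0.463), MVK falling 1.45-fold.

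The remaining lists were not called for IFNa. FOXO targets rose in 4 of 15 cases and fell in 9 (4 and 9 over the list alone, adjusted p = 0.0857), TFEB targets rose in 4 of 23 and fell in 4 (4 and 3 over the list alone, 0.701), and NRF2 targets rose in 2 of 17 and fell in 4 (1 and 3 over the list alone, 0.648). Ovarian epithelial markers rose in 3 of 15 and fell in 4 (3 and 4 over the list alone, 0.942). Of 6 fibroblast markers COL1A1 rose and COL1A2 fell (1 and 1 over the list alone, 0.605), 0 of 3 immune markers passed (0 over the list alone, median -0.20, mean 0.17, 0.942), 3 of 5 endothelial markers fell (3 over the list alone, 0.24), 1 of 15 mitochondrially encoded genes, MT-CO3, fell (1 over the list alone, 0.364) and 1 of 8 histone genes, HIST2H2AC, rose (1 over the list alone, median 0.02, tested lower with an adjusted p of 0.994).

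Adding FC-A to IFNa was compared with DMSO to give the joint response. NUPR1 rose 12.1-fold (log2 fold change 3.59, SE 0.20, n = 3 per group, adjusted p = 2.22e-09), from 214 to 2615 normalized reads. TNFSF10 rose 46.7-fold (SE 0.08, adjusted p = 4.7e-16), and CHAC1 rose 4.33-fold (SE 0.11, adjusted p = 8.06e-10). CDKN1A rose 4.96-fold (SE 0.07, adjusted p = 1.39e-12). LMO1 fell 7.56-fold (SE 0.13, adjusted p = 1.92e-10), and LGR5, a receptor of stem cells, fell 4.28-fold (SE 0.22, adjusted p = 2.04e-06).

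In the Combination 7724 genes changed against DMSO, 4167 higher and 3557 lower, and 1026 rose and 543 fell at least 2-fold. edgeR called 7783, DESeq2 7578, the authors' deposited table listed 7640 from a separate fit, and 7678 were called without replicate 3. Under quantile normalization the median of all genes was -0.111, against -0.0104 in the main analysis, and the share of higher calls went from 53.9% to 35.9%. All 52 interferon-stimulated genes (median 5.15), all 19 of MHC class I presentation (2.35) and all 11 chemokines and ligands (3.93) rose, also over each list alone, as did 16 of 19 in the receptor and JAK-STAT list with 3 not passing (list adjusted p = 1.51e-60, 6.45e-22, 1.02e-10 and 1.69e-12). Genes of the cell death list, inhibitors of death included, rose in 29 of 39 cases, fell in 5 and did not pass in 5, the same over the list alone (adjusted p = 1.02e-10). These 5 lists and the immediate early list (24 of 26 higher, adjusted p = 3.16e-14) kept their calls with an estimated correlation (adjusted p from 0.00144 to 0.0113).

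Stress targets were also higher in the Combination. Of 39 ATF4 targets 25 rose, 4 fell and 10 did not pass (26 and 4 over the list alone, median 0.42, adjusted p = 5.03e-06, or 0.146 with an estimated correlation), and ATF4 itself rose 1.58-fold (SE 0.05, adjusted p = 5.87e-08). Hypoxia and glycolysis genes rose in 16 of 19 with 3 not passing (16 over the list alone, median 0.70, adjusted p = 4.54e-06, or 0.141 with an estimated correlation). Genes of the unfolded protein response rose in 13 of 19 with 6 not passing (13 over the list alone, adjusted p = 0.000443, or 0.219 with an estimated correlation). NF-kB genes rose in 20 of 22 (20 over the list alone, adjusted p = 8.12e-14, or 0.0807 with an estimated correlation). YAP targets rose in 10 of 18 and fell in 2 (adjusted p = 0.0343, or 0.534 with an estimated correlation), estrogen receptor targets rose in 8 of 13 and fell in 2 (0.0303, or 0.111), and heat shock genes rose in 8 of 13 and 1 fell (0.0401, or 0.622), with 10 and 2, 8 and 2, and 9 and 1 over each list alone. The YAP list was lost without Combination replicate 1 (adjusted p = 0.0576) or 2 (0.0613), and the heat shock list without DMSO replicate 3 (0.0753) or Combination replicate 1 (0.105) or 2 (0.0582).

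Cell cycle genes fell in the Combination. Of 21 mitotic genes 20 fell and 1 did not pass (21 over the list alone, median -0.69, adjusted p = 2.22e-11, or 0.219 with an estimated correlation), BUB1B by 1.13 on the log2 scale. In the DNA replication and G1/S list 7 of 22 fell, 1 rose and 14 did not pass (7 and 1 over the list alone, median -0.26, adjusted p = 0.0141, or 0.646 with an estimated correlation), E2F2 by 1.69-fold (SE 0.05, adjusted p = 4.34e-08). The G1/S list was not called without Combination replicate 3 (adjusted p = 0.155), and replicate 3 of all groups was lower for 21 of these 22 genes. YWHAG, SFN, YWHAH and YWHAZ rose, with YWHAZ, YWHAB, YWHAE and YWHAQ negative and YWHAH not passing (adjusted p = 0.311) under quantile normalization, and the 14-3-3 list was not called (adjusted p = 0.0961). YWHAH was not called without DMSO replicate 3 (adjusted p = 0.0695) or Combination replicate 1 (0.0644) or 2 (0.0591).

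FC-A on top of IFNa, the step in which the series title places cell death, raised DDIT4 1.86-fold (log2 fold change 0.90, SE 0.09, n = 3 per group, adjusted p = 0.00188), from 2792 ± 383 to 5189.6 ± 484 normalized reads. BMF, the BH3-only gene that IFNa lowered, rose 1.79-fold (SE 0.13, adjusted p = 0.0151), from 424 ± 29.4 to 773 ± 180 normalized reads, against 2806 ± 197 in DMSO. CHAC1 rose 1.53-fold (SE 0.11, adjusted p = 0.031), from 461 ± 53.7 to 702 ± 48.1 normalized reads, and CDKN1A rose 1.32-fold (SE 0.07, adjusted p = 0.0273). Without IFNa, BMF and CHAC1 were also higher with FC-A, though not called. There BMF stood at 3864, 4300 and 4936 normalized reads against 2911, 2578 and 2928 in DMSO. CHAC1 stood at 253, 234.7 and 196.8 against 156, 166.5 and 161.1. CLIC5 fell 1.88-fold (SE 0.11, adjusted p = 0.00358), FLG, which encodes filaggrin, fell 1.66-fold (SE 0.08, adjusted p = 0.00292), and CPA4 fell 1.51-fold (SE 0.07, adjusted p = 0.00292).

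In all 53 genes changed, 22 higher and 31 lower. The share of higher calls was 41.5%, and it ranged with the setting from 15% without DMSO replicate 1 to 61.4% without IFNa replicate 3, with 27.9% under quantile normalization, 59.6% with DESeq2, 53.7% with the replicate block and 52.15% without replicate 3 of every group. The 4 that changed at least 2-fold fell, and they were BMPER, KCNJ15, TMEM178A and PTGER3, the last named after its values were seen. DDIT4, CLIC5, FLG and CPA4 were called with any 1 of the 12 libraries left out. The 4 genes called without IFNa replicate 1 were these same genes, and 7 were called without IFNa replicate 2. BMF was not called without IFNa replicate 1 (adjusted p = 0.105) or 2 (0.102) or Combination replicate 1 (0.0532). CDKN1A was not called without DMSO replicate 1, FC-A replicate 2, IFNa replicate 1 or 2 or Combination replicate 1 or 2 (adjusted p from 0.0561 to 0.217), and CHAC1 not without any DMSO, IFNa 1 or 2 or Combination library or FC-A replicate 2 (0.0547 to 0.217). Without replicate 3 of every group the adjusted p was 2.7e-07 for DDIT4, 0.000286 for BMF, 0.00278 for CHAC1 and 0.000194 for CDKN1A.

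**Figure D3:**
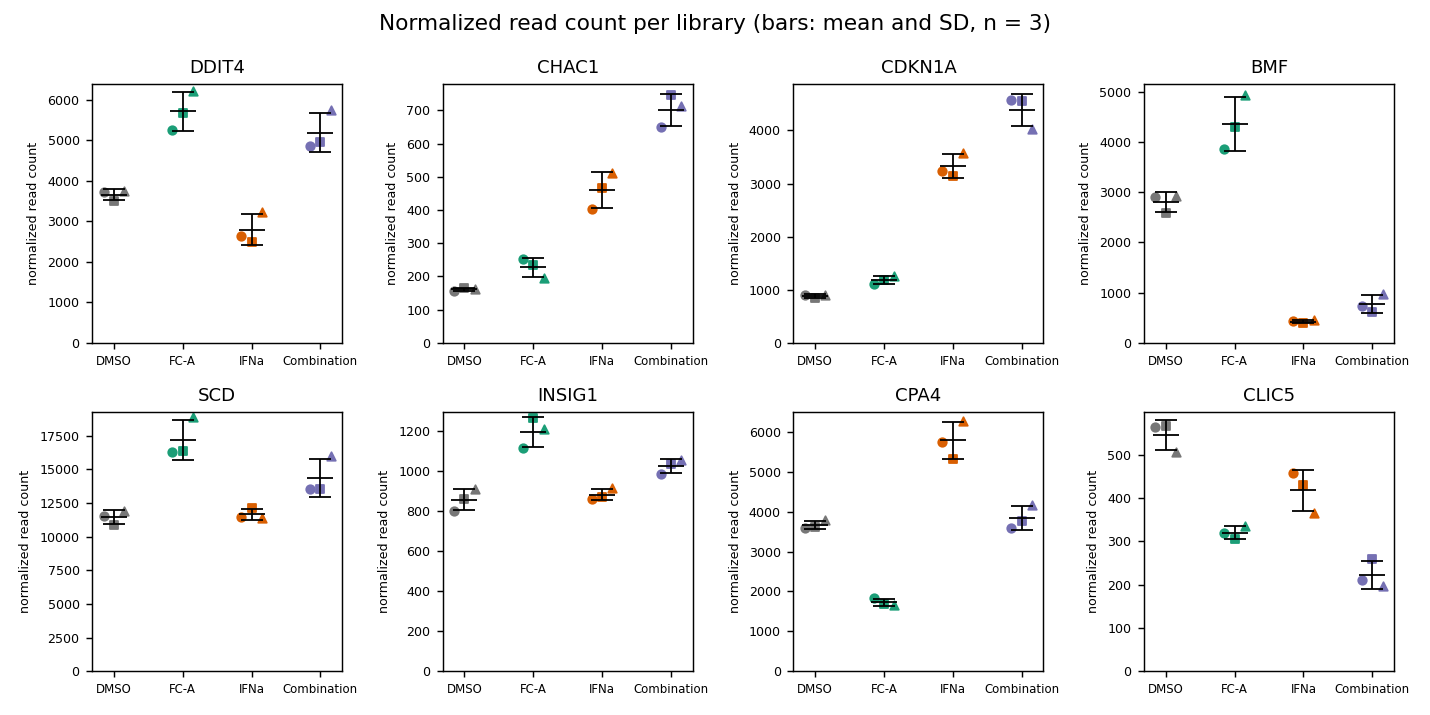
Normalized reads of 8 genes in the 4 groups (mean ± SD, with each of the 3 libraries as a point). DDIT4 averaged 3655 in DMSO, 5711 with FC-A, 2792 with IFNa and 5189.6 in the Combination, and BMF averaged 2806, 4367, 424 and 773.

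The ATF4 targets moved upward as a set here too. DDIT4 and CHAC1 rose and 37 of 39 did not pass, 17 rose when adjusted over the list alone, and 31 had positive values (median 0.13, adjusted p = 3.04e-10). That call was lost with an estimated correlation (adjusted p = 0.15) and held without replicate 3 (adjusted p = 8.91e-08). NUPR1 measured 1.01 (adjusted p = 0.0507) and ATF4 itself 0.14 (adjusted p = 0.257). In the cell death list BMF rose and 38 of 39 did not pass (4 higher over the list alone, median 0.09, adjusted p = 0.00101, or 0.0815 with an estimated correlation). TNFSF10 measured 0.32 (adjusted p = 0.139).

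With FC-A added to IFNa, 3 of the 4 interferon lists were called higher by small amounts, with 0 genes passing in each. Of 52 interferon-stimulated genes 0 passed, also over the list alone, and 50 had positive values (median 0.14, adjusted p = 8.83e-10, or 0.256 with an estimated correlation). The receptor and JAK-STAT list had a median of 0.12 (2 higher over the list alone, adjusted p = 7.9e-05, or 0.15 with an estimated correlation), and MHC class I presentation a median of 0.10 (0 over the list alone, adjusted p = 9.81e-05, or 0.297 with an estimated correlation). The 11 interferon-inducible chemokines and ligands were not called (8 positive, median 0.13, 0 over the list alone, adjusted p = 0.178, or 0.455 with an estimated correlation). Replicate 3 of all groups was higher for 16 of the 52 interferon-stimulated genes, and without it their adjusted p was 6.9e-07. Genes of the NF-kB list had a median of 0.11, CX3CL1 rising 1.38-fold, 3 higher over the list alone and 21 of 22 not passing (adjusted p = 0.00955, or 0.517 with an estimated correlation). That list was not called without Combination replicate 1 (adjusted p = 0.0762) or 2 (0.0958), and CX3CL1 not without any DMSO, Combination or FC-A replicate 2 library or IFNa replicate 1 or 2 (0.0568 to 0.29).

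Cell cycle genes were lower with FC-A added, in the direction in which replicate 3 stood apart. None of 22 DNA replication and G1/S genes passed, 1 fell when adjusted over the list alone, and all 22 had negative values (median -0.24, adjusted p = 1.91e-08, or 0.423 with an estimated correlation). Replicate 3 of all groups was lower for 21 of the 22, and the Combination libraries had list medians of -0.13, -0.14 and -0.54 against the DMSO mean, beside 0.12, 0.14 and -0.21 in the IFNa libraries, the last of each being replicate 3. The list was also called without replicate 3 of every group (adjusted p = 2.11e-12). Mitotic genes had a median of -0.11 with 0 of 21 passing (0 over the list alone, adjusted p = 1.4e-05, or 0.455 with an estimated correlation), and their call was lost without Combination replicate 3 (adjusted p = 0.0561). YAP and TEAD targets had a median of -0.21, with CRIM1 falling 1.32-fold and 17 of 18 not passing (1 over the list alone, adjusted p = 2.97e-06, or 0.256 with an estimated correlation), and replicate 3 was lower for 12 of them. CRIM1 was not called without any DMSO or Combination library, FC-A replicate 2 or IFNa replicate 1 or 2 (adjusted p from 0.0527 to 0.217). After removal of the replicate 3 axis the unadjusted cameraPR p was 0.499 for G1/S genes, 0.111 for mitotic genes and 0.0219 for YAP targets.

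**Figure D4:**
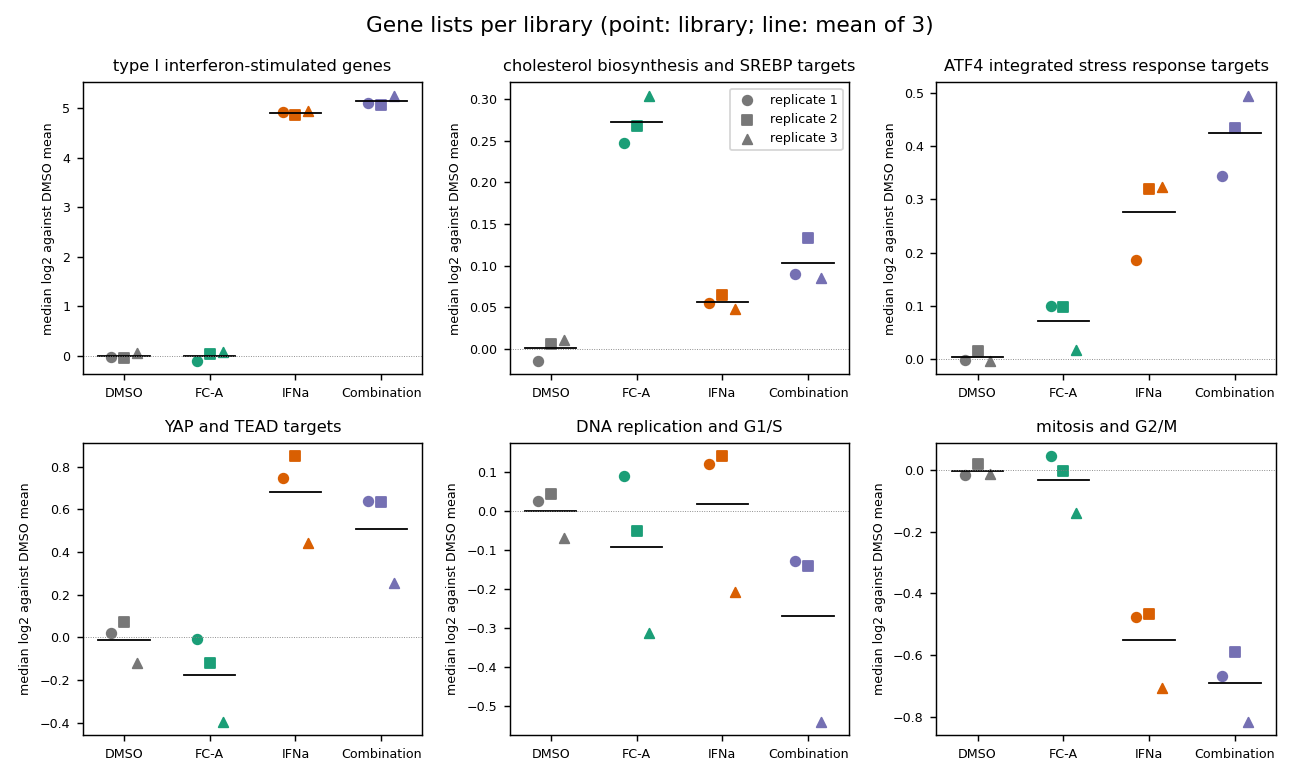
Median log2 value of 6 gene lists in each library relative to the DMSO mean, with 1 marker shape per replicate and a line at the mean of 3. Cholesterol genes lie at 0.25, 0.27 and 0.30 with FC-A and at 0.09, 0.13 and 0.08 in the Combination, and G1/S genes in the Combination at -0.13, -0.14 and -0.54.

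Other lists were called for FC-A on top of IFNa without an estimated correlation only. Hypoxia and glycolysis genes had a median of 0.29 with 0 of 19 passing (9 higher and 1 lower over the list alone, adjusted p = 2.79e-05, or 0.256 with an estimated correlation), and replicate 3 was higher for 8 of them. Histone genes had a median of 0.22 with 0 of 8 passing (3 over the list alone, adjusted p = 0.002, or 0.297 with an estimated correlation), and replicate 3 was higher for 4. Cholesterol genes had a median of 0.07 with 0 of 24 passing (6 over the list alone, adjusted p = 0.0152, or 0.256 with an estimated correlation), and their adjusted p was 0.108 without IFNa replicate 3 and 0.0958 without Combination replicate 2. NRF2 targets had a median of -0.10 (0 of 17, adjusted p = 0.029, or 0.37 with an estimated correlation) and were not called without IFNa replicate 1 (0.0689) or 2 (0.0918) or Combination replicate 3 (0.0847). Ovarian epithelial markers had a median of 0.10 (0 of 15, adjusted p = 0.0377, or 0.455 with an estimated correlation) and were not called without IFNa replicate 1 (0.126) or 2 (0.0918) or Combination replicate 1 (0.0532) or 3 (0.147). Replicate 3 was higher for 8 of those 15 markers and lower for 6 of the 17 NRF2 targets. After removal of the replicate 3 axis the unadjusted cameraPR p was 0.195 for NRF2 targets and 0.391 for the ovarian markers. It was 0.000191 for hypoxia, 0.042 for histone and 0.000503 for cholesterol genes.

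The number of genes that FC-A changed on top of IFNa varied widely with the libraries used. Without replicate 3 of every group 1187 genes were called, all 53 among them, edgeR called 55, DESeq2 240 and the authors' deposited table listed 231. Leaving out IFNa replicate 1 or 2 gave 4 or 7 genes, Combination replicate 1, 2 or 3 gave 14, 20 or 18, DMSO replicate 1, 2 or 3 gave 20, 25 or 27, FC-A replicate 1, 2 or 3 gave 92, 21 or 89, and IFNa replicate 3 gave 510. The DMSO and FC-A libraries do not enter the fold changes of this comparison, so leaving them out changed only the estimate of the spread.

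The response to IFNa on top of FC-A was compared with FC-A alone. OAS2 rose from 23.5 to 32068 normalized reads (log2 fold change 10.45, SE 0.26, n = 3 per group, adjusted p = 1.65e-13) and BMF fell 5.72-fold (SE 0.13, adjusted p = 1.14e-09). LGR5 fell 5.31-fold (SE 0.22, adjusted p = 4.79e-07). In all 7818 genes changed, 4255 higher and 3563 lower, and edgeR called 7922, DESeq2 7718 and the authors' deposited table listed 7617. Without replicate 3 the count was 7709. Under quantile normalization the median of all genes was -0.107, against -0.009 in the main analysis, and the share of higher calls went from 54.4% to 36.5%. All 52 interferon-stimulated genes rose (median 5.06, adjusted p = 7.46e-60, or 0.00329 with an estimated correlation), and 5 of 24 cholesterol genes rose while 12 fell and 7 did not pass (5 and 12 over the list alone, adjusted p = 0.101). The 14-3-3 list had 4 of 7 genes higher and an adjusted p of 0.0371, or 0.455 with an estimated correlation, but 0.968 under quantile normalization, where YWHAZ, YWHAB, YWHAE and YWHAQ turned negative, 0.0848 without FC-A replicate 3 and 0.0689 without Combination replicate 1.

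FC-A and IFNa given singly were also set against each other. BMF was 10.2-fold higher with FC-A than with IFNa (log2 fold change 3.36, SE 0.13, n = 3 per group, adjusted p = 4.4e-11), and RBBP8NL was 6.10-fold higher (SE 0.14, adjusted p = 1.3e-09). BMF stood at 3864 to 4936 normalized reads with FC-A, 2578 to 2928 in DMSO and 393.1 to 451.7 with IFNa. MX1, an antiviral GTPase, was 230-fold lower with FC-A than with IFNa (SE 0.10, adjusted p = 1.53e-16). It stood at 474 to 688.9 normalized reads with FC-A, 616.1 to 748.5 in DMSO and 134200 to 139400 with IFNa. That gap is thus mostly the rise with IFNa. Of 7927 genes that differed, 3612 were higher and 4315 lower with FC-A, edgeR called 8052, DESeq2 7822 and the authors' deposited table listed 7712, and without replicate 3 the count was 7902. All 52 interferon-stimulated genes were lower with FC-A than with IFNa (median -4.90, adjusted p = 2.55e-59, or 0.00339 with an estimated correlation), while none of them passed for FC-A against DMSO. Cholesterol genes were higher in 12 of 24, lower in 4 and did not pass in 8 (12 and 4 over the list alone, median 0.25, adjusted p = 0.0295, or 0.248 with an estimated correlation). The share of higher calls went from 45.6% to 62.2% under quantile normalization.

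Whether FC-A acted differently with IFNa present was tested as the interaction. limma called 0 genes, with 627 at an unadjusted p under 0.05 where chance gives 799.5, a smallest adjusted p of 0.593 and a median SE of 0.131. The number at an unadjusted p under 0.05 lay above that of chance in some settings, with 1748 without replicate 3, 1309 with a term for it, 1260.0 with the replicate block, 1234 without IFNa replicate 3 and 1091 without FC-A replicate 3, and below it (477 to 746) with any other library left out. edgeR called 0, and DESeq2 called 3, among them KLHL29 and CPA4. Without replicate 3 limma called 1 gene, NOV, named after its values were seen. CPA4 measured 0.49 (SE 0.10), KLHL29 0.41 (SE 0.07) and FAM65B 1.36 (SE 0.24), all with an adjusted p of 0.593. DDIT4 measured 0.26, BMF 0.21 and CHAC1 0.12, each with an adjusted p above 0.99. As a set, the 24 cholesterol genes responded less to FC-A when IFNa was present (median -0.20, 23 negative, 0 genes passing and 9 lower over the list alone, adjusted p = 2.61e-17, or 0.00284 with an estimated correlation). Of 28 lists, 9 were called for the interaction, and the cholesterol list alone kept its call with an estimated correlation.

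Across genes, which are not independent replicates, the FC-A effects without and with IFNa had a Pearson correlation of 0.263 and a Spearman correlation of 0.339, and without replicate 3 the former was 0.134. The 2 comparisons share no library, but both use the variance that limma estimated for each gene over all 12 libraries. Their calls are therefore not independent, and the expected counts given here hold for independent calls only. DDIT4, CDKN1A, CIC and SAMD4B rose in both (4 genes, 0.0344 expected of independent calls), CIC and SAMD4B being named after their values were seen, and 12 genes fell in both (0.0446 expected), among them CPA4, CLIC5, RGCC, PCDH19 and IQGAP2. No gene called in both went opposite ways, and 45 of the 48 genes called for FC-A alone had the same sign on top of IFNa. The IFNa effects without and with FC-A had a Pearson correlation of 0.949, or 0.918 without replicate 3, with 3617 genes higher in both (1082 expected) and 2685 lower in both (767 expected).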

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

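Of the tests given here, that of the G1/S list on the axis of replicate 3 was chosen before its result was seen, and the other tests were applied to these patterns after the result was seen, although the scalings and the left-out libraries were themselves planned before the data were examined.

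Among lists whose response to FC-A differed with and without IFNa, cholesterol synthesis stood out (adjusted p = 2.61e-17, median -0.20, or 0.00284 with an estimated correlation). The genes were higher with FC-A alone and less so when IFNa was present. Other readings were tested: the adjusted p was 7.141e-17 at most when the authors' scaling was replaced, a single left-out library gave 3.879e-12 at most (without IFNa replicate 3), and the p after removal of the replicate 3 axis was 4.24e-23. None of the 24 genes passed the interaction test by itself, so which sterol genes respond less stays open.

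The list of DNA replication and G1/S differed as well (adjusted p = 0.000426, or 0.634 with an estimated correlation, 0.135 without FC-A replicate 1 and 0.679 without Combination replicate 3). These genes were lower in the Combination than with IFNa, and without replicate 3 of every group that decrease had an adjusted p of 2.109e-12, which argues against the replicate 3 libraries as its only source. After the replicate 3 axis was removed its p was 0.499 and the median went from -0.24 to -0.09, so the decrease may lie on that axis of genes. The list medians were -0.13, -0.14 and -0.54 in the Combination and 0.12, 0.14 and -0.21 with IFNa, so replicates 1 and 2 show the decrease too. Whether it is an effect of FC-A that runs along the same axis stays open.

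The ATF4 targets were higher with FC-A without and with IFNa. Replicate 3 does not account for it (highest adjusted p without it 8.906e-08), nor does a single library (0.0006794 at most, without FC-A replicate 1) or the scaling (1.146e-07 at most). With an estimated correlation the adjusted p was 0.247 and 0.15, so a shared movement of these genes between libraries could give the same result. Most members did not pass singly, and that reading stays open.

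The other lists whose FC-A response differed are given as values. Type I interferon-stimulated genes had an adjusted p of 3.02e-07 (median 0.09, 6 higher over the list alone, 0.429 with an estimated correlation). The receptor and JAK-STAT list had 0.0129 (median 0.07, 0.429 with an estimated correlation, 0.055 without FC-A replicate 1, 0.191 without IFNa replicate 2). MHC class I presentation had 5.83e-05 (median 0.11, 0.429 with an estimated correlation). Interferon-inducible chemokines and ligands also had 5.83e-05 (median 0.29, 0.0567 with an estimated correlation). Several of these genes had few reads without IFNa, such as CXCL11 at 0 to 1.782 normalized reads. Their FC-A response without IFNa, which enters this value, therefore rests partly on values near 0. The cell death list had 0.00188 (median 0.10, 0.0505 with an estimated correlation). Mitotic genes had 0.00147 (median -0.09, 0.634 with an estimated correlation, 0.147 without IFNa replicate 2, 0.591 without Combination replicate 3). Mitochondrially encoded genes had 0.00049 (median 0.16, 0.629 with an estimated correlation, 0.147 without IFNa replicate 2). After removal of the replicate 3 axis the unadjusted cameraPR p was 0.115 for mitotic genes. For the other lists of this paragraph it ran from 4.06e-07 (chemokines and ligands) to 0.0168 (receptor and JAK-STAT).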

How the results depend on the processing

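With 31.2 to 39.5 M reads per library and 3 libraries per group, depth limited genes below a mean of 10 normalized reads. Every alternative chosen was run. For results that moved, the cause was not tested.

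For FC-A against DMSO, where limma called 48 genes, the count was 20 without a variance trend, 26 with the compared groups only, 289 with the replicate number as a block, 134 without replicate 3 of every group, 336 with a term for replicate 3, 171 with DESeq2, 3 at a fold of at least 2 and 155 in the authors' deposited table. Leaving out 1 library gave 16 (without DMSO replicate 2) to 119 (without FC-A replicate 1). For the Combination against IFNa, with 53 genes, the same settings gave 11, 10, 1009, 1187, 1110, 240, 4 and 231, and leaving out 1 library gave 4 (without IFNa replicate 1) to 510 (without IFNa replicate 3). The main analysis without the block was set before the data were examined. The labels give no shared origin for libraries of the same number, and 10 of 18 such pairs had a correlation of deviations over 0.1, where all were required to treat the numbers as pairs. The median correlation was 0.11 for the same number, against -0.0819 for different numbers, and 0.26 (0.188 to 0.395) for replicate 3, so replicate 3 deviates together across groups. In all, 7 of 12 libraries were nearest to one of their own number.

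At a fold of at least 2 the counts were 1439 for IFNa against DMSO, 1569 for the Combination against DMSO, 1573 against FC-A and 1574 for FC-A against IFNa. The interaction had 1 gene with the block, 1 without replicate 3 (NOV), 7 with a term for replicate 3 (among them KLHL29, FAM65B, CPA4, NOV, LIPA and ETS2) and 3 with DESeq2 (among them KLHL29 and CPA4).

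The correlation of the FC-A effect without and with IFNa, 0.263 in the main analysis, was 0.343 with a pseudocount of 8, 0.0652 with no filter, 0.474 at a minimum mean of 50, 0.134 without replicate 3 and 0.0792 (without FC-A replicate 3) to 0.361 (without FC-A replicate 1) with 1 library left out. That of the IFNa effect, 0.949, was 0.962, 0.755, 0.979 and 0.918 in the same order, and 0.931 at the lowest with 1 library left out (IFNa replicate 3).

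Signs reversed in a few results. The first was a gene list: DNA replication and G1/S, FC-A vs DMSO, which without FC-A replicate 3 was on the higher side (adjusted p = 0.878), the range with 1 library left out being 0.000485 (without FC-A replicate 1) to 0.878. Under quantile normalization IFNa against DMSO gave YWHAB -0.19, YWHAE -0.25, YWHAQ -0.16, YWHAZ -0.13 and GCN1L1 -0.18. The Combination against DMSO gave MT-RNR1 -0.0252, YWHAB -0.22, YWHAE -0.28, YWHAQ -0.21, YWHAZ -0.11 and GCN1L1 -0.21, and against FC-A YWHAB -0.18, YWHAE -0.19, YWHAQ -0.18, YWHAZ -0.0748 and GCN1L1 -0.27. FC-A against IFNa gave YWHAZ 0.0921, YWHAB 0.15, YWHAE 0.17 and GCN1L1 0.23.

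Of 196 list results, 64 lost their call with an estimated correlation, and 24 lost and 23 gained one with fry. Quantile normalization ended 8 and added 3, and leaving out replicate 3 ended 4 and added 13. Of 495 named gene results, 40 lost their call without a variance trend, 27 under quantile normalization, 4 with edgeR and 2 with DESeq2, and 7 to 35 with 1 library left out.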

Other observations

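Of the tests weighed here, the splits of libraries, the single libraries left out, DESeq2 and the replicate block were chosen before their results were seen, and the settings without replicate 3 of every group and with a term for replicate 3 were chosen after the data were seen.

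At 6 h IFNa alone set the state of these cells, with TNFSF10 up 37.4-fold and BMF down 6.60-fold, and FC-A changed 48 genes without it and 53 with it in the main analysis. Those near-equal counts did not last: without replicate 3 they were 134 and 1187, and leaving out 1 library moved the second from 4 to 510. FC-A raised DDIT4 and lowered CPA4 and CLIC5 in both settings. On top of IFNa it raised BMF 1.79-fold and CHAC1 1.53-fold, 2 genes tied to cell death and glutathione loss, but neither call held with each library left out in turn. Without IFNa both genes were also higher in every FC-A library than in every DMSO library, though not called. Their interaction values of 0.21 and 0.12 did not pass. limma called 0 genes for the interaction in the main analysis, against 3 with DESeq2, 1 with the replicate block, 1 without replicate 3 and 7 with a term for replicate 3, and sterol genes as a set responded less to FC-A with IFNa present (median -0.20).

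The splits of 6 libraries into 3 and 3 are too few to rule out chance, since only 10 exist and 1 of them is the real one. The real and the highest other count were 48 and 1 for FC-A against DMSO, 7507 and 0 for IFNa, 7724 and 0 for the Combination against DMSO, 53 and 0 against IFNa, 7818 and 0 against FC-A, and 7927 and 0 for FC-A against IFNa. For the interaction the real count was 0, so all 100 assignments had to reach it and that share tells nothing about chance. Apart from that share, the highest count of a reassignment was 2171, which may point to a structure of the samples, but which structure that reassignment followed was not tested. The absolute correlation of the FC-A effect without and with IFNa (0.263) was reached by 15 of 100 pairs of splits, the real pair included, the highest being 0.44. In that highest pair both replicate 3 libraries lay on the same side in each comparison, so it can carry the deviation that replicate 3 shared across groups. The size of the correlation alone therefore does not show a shared FC-A effect, and the splits cannot tell how often chance would reach it.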
